A study of Mus musculus with 2 samples.

How the data were processed

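Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used on embryonic mouse hindbrain at day 15.5 with an antibody against histone H3 trimethylated at lysine 4 (H3K4me3), a mark found mainly at promoters. The series has 1 group with 2 biological replicates, each a separate pool of tissue from B6NCrl embryos (78 embryos in replicate 1 and 62 in replicate 2), per the labels. Fragments of 300 to 500 bp were used, per the labels. There is no second tissue, stage or treatment, so every comparison was made between the replicates or between groups of genes and peaks within the lists.

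The analysis started from 4 deposited peak lists in narrowPeak format on the mm10 build. The 2 replicate lists were made by the authors from the alignments of each replicate and a control, per the deposited text notes. The pooled list was made from the alignments of both replicates, and the replicated list from the pooled list and both replicate lists, per the deposited text notes. The aligner, the peak caller, its version and its threshold are not given in the sources used here. The lowest −log10 p was 2.02 in replicate 1 and 2.04 in replicate 2, and the lowest −log10 q 0.192 and 0.218. In these lists 1788 and 1902 peaks had a −log10 q below 2, so a gene can be marked by a very weak peak. Each peak carries an enrichment value, read here as a fold ratio over control, which the authors deposited. The authors also deposited −log10 p and −log10 q values per peak. These values are the authors' own, and were used only to describe, rank or filter peaks within a list. The lists give no read counts, so the depth of each replicate is unknown, and no interval or floor that needs read numbers was computed. Intervals on shares of genes or peaks are exact 95% Clopper-Pearson intervals and treat genes or peaks as independent, which neighbouring genes are not.

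Gene positions came from the GENCODE vM21 annotation and sequence from the GRCm38.p6 assembly, which is the same build: 0 peaks ended beyond their chromosome. The 21938 protein-coding genes on chromosomes 1 to 19, X and Y were used. A gene was called marked when a peak lay within 1000 bp of any of its annotated transcription start sites (TSSs). A gene said to have no peak had none in this window, and peaks elsewhere in its body were not counted. Peaks separated by at most 1000 bp were joined into a domain, and the breadth of a gene was the span of the widest domain touching its TSS window. Several genes can share a domain: 3054 of 14545 marked genes did. A broadest domain was one in the top 5% of marked genes. A distal peak lay more than 5000 bp from any annotated TSS. Promoter CpG content was the observed over expected CpG ratio within 500 bp either side of the 5' end of the gene. The widest domain of a gene can lie away from this 5' end and touch another annotated TSS, as at Nfib, Elavl2, Elavl4, Lhx2 and Ptch1 among others. For such genes CpG content was not measured at the domain. Positions are given as a genome browser shows them.

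Peak lists were compared by overlap of at least 1 bp, beside 100 random placements of the peaks within their chromosomes. Marked shares were compared with two-sided Fisher's exact tests, and median breadths with two-sided permutation tests of 100000 resamples. The smallest possible p is 2e-05 for a list against other marked genes and 1e-05 between named groups of genes. P-values were adjusted with the Benjamini-Hochberg method over the 27 gene lists (20 lists with at least 10 marked genes for breadth), with a threshold of 0.05. Tests between gene groups take genes as units and say nothing of variation between embryos, which 2 replicates cannot give. The tests of the lists against other genes and those of Hox and X-linked genes were therefore repeated on the list of each replicate alone, while the CpG-matched tests, the logistic model and the test of left-out peaks were not.

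The gene lists, the tests, the rule for naming genes and all alternatives, except those named as added, were fixed before the data were examined. The lists covered hindbrain regional regulators, rhombic lip and granule cell genes, Purkinje and cerebellar GABAergic genes, brainstem neuron transcription factors, transmitter synthesis and transport genes, and pan-neuronal, neural progenitor, oligodendrocyte and astrocyte genes. Further lists held forebrain and midbrain regulators, the Sonic hedgehog pathway, cell cycle, housekeeping, imprinted, Hox, ribosomal protein and clustered protocadherin genes, and non-neural transcription factors. Markers of other cells and tissues were microglia and macrophages, endothelium and pericytes, meninges and choroid plexus, erythroid cells, liver, gut and pancreas, and muscle, cartilage, bone and skin. Olfactory receptors, vomeronasal receptors and keratin-associated proteins served as families used outside the brain. Drgx (34 of 35 brainstem genes found) and Ahsp (15 of 16 erythroid genes found) had no protein-coding gene of that symbol in the annotation, and Meg3 is not annotated as protein-coding (19 of 20 imprinted genes used). The genes named are those of the 10 broadest domains, every Hox gene, and the 3 genes of highest enrichment marked in 1 replicate only. The 5 distal peaks of highest enrichment are given as well. For part of the lists only, the 2 broadest members and up to 3 members without a peak in either replicate are named. Other genes named were members of a short count or examples of a list, and were chosen after their values were seen.

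The alternatives were each replicate alone, the pooled list, a −log10 q of at least 5, TSS windows of 500 and 2500 bp, the 5' end of the gene as the only TSS, no joining of peaks or joining over 3000 bp, bases covered in place of span, each domain given to the nearest gene only, and a background matched on deciles of promoter CpG with 10000 draws. Overlaps of 50% of the peak or of both peaks, equal numbers of peaks, the −log10 p in place of enrichment, the broadest 10% and distal limits of 2500 and 10000 bp were also tried. The functions were tested on simulated data. With marks placed at random on the 21938 genes, 4.15% of 2700 occupancy tests had a raw p under 0.05, and 67 of 100 lists given a marked share of 95% were called. With breadths of replicate 1 shuffled over its 14597 marked genes, 5.89% of 475 permutation tests had a raw p under 0.05, and 474 of 475 lists made 2 times as broad did. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9. Scaffolds other than the chromosomes above were left out of the gene tests.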

Results

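H3K4me3 was mapped by ChIP-seq in hindbrain of mouse embryos at day 15.5, a stage at which the cerebellum and the brainstem nuclei are forming. The data comprise 2 biological replicates of 1 group, pooled from 78 and 62 embryos, with 27751 and 28489 peaks. A pooled list held 29727 peaks and the replicated list 23740 peaks. The peaks of the replicates covered 38.8 and 40.0 Mb with median widths of 1101 and 1072 bp. Their median enrichment over control was 14.9 and 13.1. Read depth is unknown from these lists. Values below are from the replicated list unless a replicate is named.

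The replicates marked nearly the same promoters. Of 21938 protein-coding genes, 14495 had a peak at a TSS in both replicates, 102 in replicate 1 only, 83 in replicate 2 only and 7258 in neither, so 98.7% (95% interval 98.5 to 98.9) of the genes marked in either were marked in both (kappa = 0.981). Domain breadth in replicate 1 and replicate 2 lay within 1.5-fold for 96.0% of the genes marked in both, with Spearman's rho = 0.94 across genes. The enrichment values at the same promoters ranked less alike, with rho = 0.662 (95% bootstrap interval 0.651 to 0.671). Genes are not independent replicates, and no p was computed for these correlations. Genes marked in 1 replicate only had mostly weak peaks, with a median enrichment of 3.15 in replicate 1 and 3.13 in replicate 2, against 40.0 and 36.1 for genes marked in both. Of these 185 genes 145 rested on a peak with a −log10 q under 5 and 40 did not. The highest enrichment was at Gm20538 (56.0), Sftpc (49.8) and Hrc (42.95) in replicate 1 and at Clec11a (42.3), AC141477.1 (38.2) and Astl (29.7) in replicate 2. Gm20538, Sftpc, Hrc and Astl shared their domains with Ndufb8, Bmp1, Trpm4 and Dusp2, whose TSSs lay nearer the domain centres.

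At the level of peaks, 24738 of 27751 peaks of replicate 1 (89.1%, 88.8 to 89.5) and 24348 of 28489 peaks of replicate 2 (85.5%, 85.0 to 85.9) overlapped a peak of the other. Random placements gave at most 3.47% and 3.37%. The overlap in bases had a Jaccard index of 0.842. Peaks without a partner were narrow, with median widths of 238 and 244 bp against 1317 and 1388 bp for shared peaks. Their highest enrichment was 7.24 in replicate 1 and 7.91 in replicate 2. Among peaks with a −log10 q of at least 5, the shared part rose to 94.8% of 21331 and 93.2% of 21600 peaks.

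The replicated list left out 5987 of the pooled peaks, and these were less often at promoters than the retained ones. Of the peaks left out, 1174 (19.6%) were within 1000 bp of a protein-coding TSS, against 15173 of 23740 retained peaks (63.9%), with an odds ratio of 0.138. The one-sided hypergeometric tail of this table, as in Fisher's exact test, had a −log10 p of 857. With a 2500 bp window the part of the left-out peaks near a protein-coding TSS was 47.6%, against 70.0% of the retained ones (odds ratio 0.389). The peaks left out had a median width of 247 bp and a median enrichment of 2.51, against 1552 bp and 25.2 for those retained. Only 37 of the peaks left out touched a peak in both replicates, while 3619 touched a peak in 1 and 2331 in neither. The replicated list was made with both replicate lists, so this split follows at least in part from how peaks were retained.

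H3K4me3 peaks lay at promoters in every list. In the replicated list 16488 peaks (69.5%) were within 1000 bp of the TSS of any gene, where random placements gave a mean of 10.7% and at most 11.0%. The share was 64.1% in replicate 1 and 62.8% in replicate 2. The list marked 14545 of 21938 protein-coding genes (66.3%, 65.7 to 66.9), and the replicates alone marked 14597 and 14578. Marking followed promoter CpG content. In the lowest CpG quartile 611 of 5485 genes (11.1%, 10.3 to 12) were marked, in the second 57.2%, in the third 97.2%, and in the highest 5465 of 5485 (99.6%, 99.4 to 99.8).

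Genes of 6 lists of neurons, neural progenitors and hindbrain regulators were almost all marked. Pan-neuronal genes were marked in 30 of 30 cases (88.4 to 100%), neural progenitor genes in 24 of 24 (85.8 to 100%), brainstem neuron transcription factors in 33 of 34 (84.7 to 99.9%) and hindbrain regional regulators in 23 of 24 (78.9 to 99.9%). Rhombic lip and granule cell genes and Purkinje and cerebellar GABAergic genes were each marked in 25 of 26 cases (80.4 to 99.9%). The exceptions were Dbx1, a homeobox gene of interneuron progenitors, Hnf1b, an early regulator of the caudal hindbrain, Gabra6, a receptor subunit of mature granule cells, and Pcp2, a gene of maturing Purkinje cells, and none of these had a peak in either replicate. Each of these lists exceeded the share of about 66.3% among other genes, with adjusted p from 2.4e-05 (pan-neuronal) to 0.0014 (hindbrain regional) by Fisher's exact test. Each had the same number of marked genes in both replicates alone.

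Several other lists were also marked more often than other genes. Sonic hedgehog pathway genes (14 of 14, adjusted p = 0.0059), cell cycle genes (20 of 20, adjusted p = 8.9e-04), housekeeping genes (25 of 25, adjusted p = 1.4e-04) and ribosomal protein genes (80 of 83, adjusted p = 1.9e-10) passed Fisher's exact test. The 3 unmarked ribosomal genes were the copies Rpl10l, Rpl39l and Rpl3l. Forebrain and midbrain regulators, such as Foxg1 and Otx2, were marked in 27 of 27 cases (adjusted p = 6.2e-05, Fisher's exact test), with 26 of 27 in each replicate alone. Imprinted genes were marked in 18 of 19 cases, all but Ndn (adjusted p = 0.0091), a call lost with the 5' end as the only TSS (adjusted p = 0.20, Fisher's exact test). Endothelial and pericyte genes were marked in 18 of 20 cases, with no peak at Slco1c1 or Tie1 (adjusted p = 0.041), and this call was lost in replicate 2 alone (17 of 20, adjusted p = 0.12), with a −log10 q of at least 5 (adjusted p = 0.31) and with the 5' end only (adjusted p = 0.20), all by Fisher's exact test.

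Part of these calls no longer passed against genes matched on CpG content. Against other genes matched on promoter CpG, granule cell genes (96.2% against 79.6%), brainstem transcription factors (97.1% against 86.3%), pan-neuronal genes (100% against 81.9%), endothelial genes (90.0% against 66.7%) and imprinted genes (94.7% against 76.9%) still stood out. The adjusted p over the 27 lists ranged from 0.0027 (granule cell) to 0.027 (brainstem) in this permutation test. The other 8 lists no longer passed, hindbrain regional regulators among them (95.8% against 91.4%, adjusted p = 0.76, permutation test). Neural progenitor (against 90.0%), forebrain and midbrain (91.3%), housekeeping (89.0%), Sonic hedgehog (95.1%) and cell cycle genes (98.1%) did not pass although 100% were marked. At such matched shares these lists had no room to pass. For them the test cannot tell whether CpG content accounts for the calls, and hindbrain regulators had little room as well.

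Genes of glia and transmitter use did not pass the test against other genes. Astrocyte genes were marked in 12 of 16 cases (adjusted p = 0.71, Fisher's exact test), with peaks at Aldh1l1, Gja1 and Slc1a2 and none at Agt, Gfap or S100b. Oligodendrocyte genes were marked in 12 of 18 (adjusted p = 1, Fisher's exact test). Olig2 and Pdgfra, which act in oligodendrocyte precursors, were among them, as were the myelin genes Mbp (2515 bp), Cnp (1926 bp) and Cldn11 (1118 bp), with Bcas1, Myrf and Ugt8a. The myelin genes Mag, Mobp, Mog and Plp1 and the genes Gpr17 and Opalin had no peak in either replicate. Transmitter synthesis and transport genes were marked in 14 of 20 (adjusted p = 0.85, Fisher's exact test), including the transporters Slc17a6 and Slc32a1 of glutamatergic and inhibitory neurons. Of the genes of monoamine use, the enzyme Ddc (519 bp) and the transporters Slc18a2, Slc6a2 and Slc6a4 were marked in both replicates, and the enzymes Dbh, Hdc, Pnmt, Th and Tph2 had no peak in either.

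Genes of blood, liver, muscle and sensory families were rarely marked. Microglia and macrophage genes were marked in 2 of 18 cases, Hexb and Irf8 (adjusted p = 8.8e-06), and erythroid genes in 3 of 15, Epor, Gypa and Rhd (adjusted p = 6.6e-04, Fisher's exact test). Aif1, C1qa and C1qb, and Alas2, Ermap and Hba-a1, had no peak in either replicate. Liver, gut and pancreas genes were marked in 1 of 26 cases, Apoh, which shared its domain with Prkca (adjusted p = 1.8e-10, Fisher's exact test). Muscle, cartilage, bone and skin genes were marked in 8 of 26 (adjusted p = 5.7e-04, Fisher's exact test): Acan, Ckm, Col2a1, Krt1, Krt10, Matn3, Mylpf and Ryr1, of which Mylpf and Ckm shared domains with Tbc1d10b and Klc3. Of 1093 olfactory receptors 3 were marked (Olfr1033, Olfr658 and Olfr94; 0.274%, 0.0566 to 0.80%). Of 327 vomeronasal receptors only Vmn1r4 was marked, in a domain shared with Nt5c3, and of 57 keratin-associated genes only Krtap17-1 (adjusted p = 2.4e-153 and 1.1e-24, Fisher's exact test). Members of these families have near-identical copies, so their values are uncertain. Against CpG-matched genes the calls for microglia (adjusted p = 0.053), erythroid (adjusted p = 1) and muscle genes (adjusted p = 0.25) were lost in the permutation test.

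Meninges and choroid plexus genes (12 of 20, adjusted p = 0.72), non-neural transcription factors (28 of 40, adjusted p = 0.80), Hox genes (32 of 39, adjusted p = 0.053) and clustered protocadherins (45 of 57, adjusted p = 0.060) did not pass Fisher's exact test either. Of the choroid plexus and connective tissue genes, Clic6, Enpp2, Foxj1, Kl, Col1a1 and Col1a2 were marked in both replicates, and Aqp1, Folr1, Kcne2, Slc4a5, Ttr, Dcn and Lum had no peak in either. Hox genes passed in replicate 1 alone (33 of 39, adjusted p = 0.021) and with a 2500 bp window (adjusted p = 0.034, Fisher's exact test). Clustered protocadherins passed in each replicate alone, with 49 and 51 of 57 marked (adjusted p = 0.0017 and 2.6e-04, Fisher's exact test), and also in the pooled list, with a 500 bp window and with the 5' end only. They did not pass with a −log10 q of at least 5, with a 2500 bp window or against CpG-matched genes (78.9% against 78.8%, adjusted p = 1, permutation test).

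**Figure D1:**
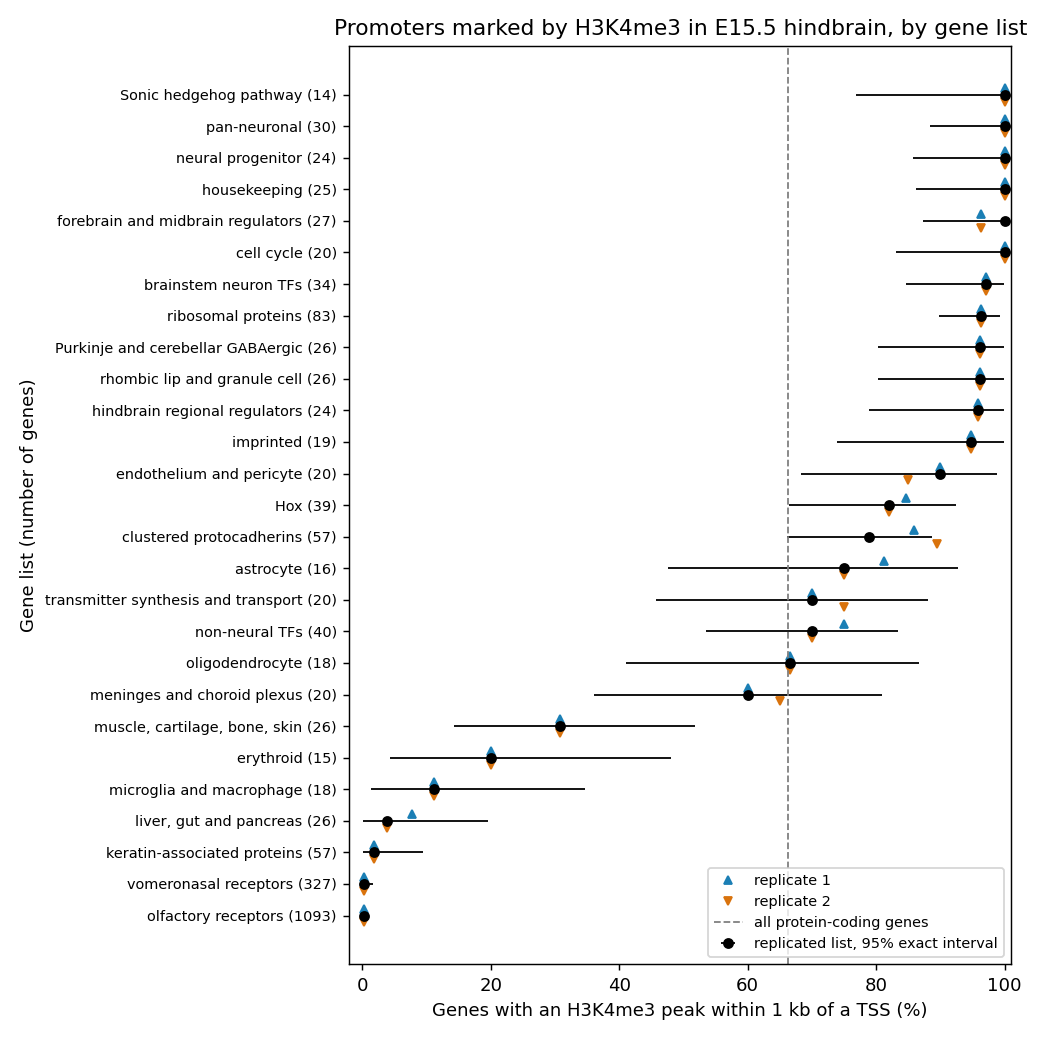
Share of genes with an H3K4me3 peak within 1 kb of a TSS (x axis, %) for each of the 27 gene lists (y axis, with the number of genes). Black points with bars are the replicated list with exact 95% intervals, triangles the 2 replicates alone, and the dashed line the 66.3% of all protein-coding genes, with the neural lists to its right and olfactory receptors at 0.274%.

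Broad promoter domains lay at regulators of hindbrain and neural development. Hindbrain regional regulators had a median breadth of 6268 bp, 2.64 times the 2379 bp of other marked genes, and the replicates alone gave 6097 and 6579 bp. Meis2 and Meis1, homeobox partners of Hox proteins, had the broadest domains of this list, at 25828 ± 1938 and 15456 ± 7.8 bp (mean ± SD of the replicates, n = 2). Rhombic lip and granule cell genes had a median of 5646 bp, led by Zic1 and Zic4, which share a domain of 22219 ± 793 bp (SD, n = 2). Purkinje and cerebellar GABAergic genes had a median of 5632 bp, led by Ebf3 (23167 ± 266 bp, SD, n = 2) and Lhx1 (19324 ± 1402 bp, SD, n = 2). Neural progenitor genes had a median of 5515 bp, led by Pax6 (16159 ± 1239 bp, SD, n = 2) and Pax3 (11146 ± 448 bp, SD, n = 2). All 4 lists were broader than other marked genes (p = 2e-05 for each, the smallest that the resamples can give, and adjusted p = 5e-05, permutation test).

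Other lists differed in breadth as well. Astrocyte genes (median 4860 bp, with Nfib at 20312 ± 21.9 and Nfia at 9844 ± 20.5 bp, SD, n = 2) and pan-neuronal genes (median 4666 bp, with Elavl4 at 10932 ± 704 and Elavl2 at 9742 ± 510 bp, SD, n = 2) were broader than other marked genes, with adjusted p = 5e-05 for each in the permutation test. Sonic hedgehog pathway genes had a median of 4418 bp (adjusted p = 3.1e-04, permutation test), with Mycn at 6260 ± 378 bp and the receptor Ptch1 at 7820 bp in replicate 1 and 12467 bp in replicate 2. Imprinted genes had a median of 3678 bp (adjusted p = 0.0024, permutation test), and Peg3 among them measured 7194 ± 131 bp (SD, n = 2). Nnat measured 8218 bp in the replicated list, and 3997 and 4088 bp in the replicates alone. Hox genes had a median of 4557 bp (adjusted p = 5e-05, permutation test), a call lost with each domain given to the nearest gene only (ratio 0.949, adjusted p = 0.67, permutation test). Clustered protocadherins were narrower, at 885 bp against 2384 bp in other marked genes (adjusted p = 5e-05, permutation test), and measured 676 and 646 bp in the replicates.

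The remaining 10 lists did not pass the permutation test against other marked genes. Brainstem neuron transcription factors had a median of 2904 bp (adjusted p = 0.083, permutation test), though in replicate 2 alone they passed as broader, at 3400.0 bp (adjusted p = 6.0e-04), as they did in the pooled list (adjusted p = 5e-05), with a 500 bp window (adjusted p = 0.018), with joining over 3000 bp (adjusted p = 5e-05) and against CpG-matched genes (adjusted p = 0.038, permutation test). Their broadest members were Gata3 (16045 ± 76.4 bp, SD, n = 2) and Lmx1b (14588 ± 2675 bp, SD, n = 2). Forebrain and midbrain regulators had a median of 1971 bp, 0.828 times that of other genes (adjusted p = 0.11, permutation test). In replicate 1 alone their median was 1403 bp and they passed as narrower (adjusted p = 3.1e-04, permutation test), as they did with a −log10 q of at least 5, the 5' end only, no joining and bases covered. In contrast, joining over 3000 bp turned the ratio to 1.61 (adjusted p = 5.1e-04, permutation test). Bcl11b (8820.5 ± 44.5 bp) and Lhx2 (9260.0 ± 974 bp, SD, n = 2) were the broadest of them. Medians were 2948 bp for housekeeping, 2808 bp for meninges and choroid plexus, 2787 bp for transmitter, 2584 bp for ribosomal protein and 2498 bp for oligodendrocyte genes. They were 2322 bp for endothelial, 2255 bp for cell cycle and 2166 bp for non-neural transcription factor genes. Adjusted p for these 8 lists ranged from 0.10 to 0.83 in the permutation test. Non-neural transcription factors passed as narrower with the 5' end only or without joining, housekeeping genes as broader in the pooled list, and housekeeping and transmitter genes as broader with joining over 3000 bp.

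**Figure D2:**
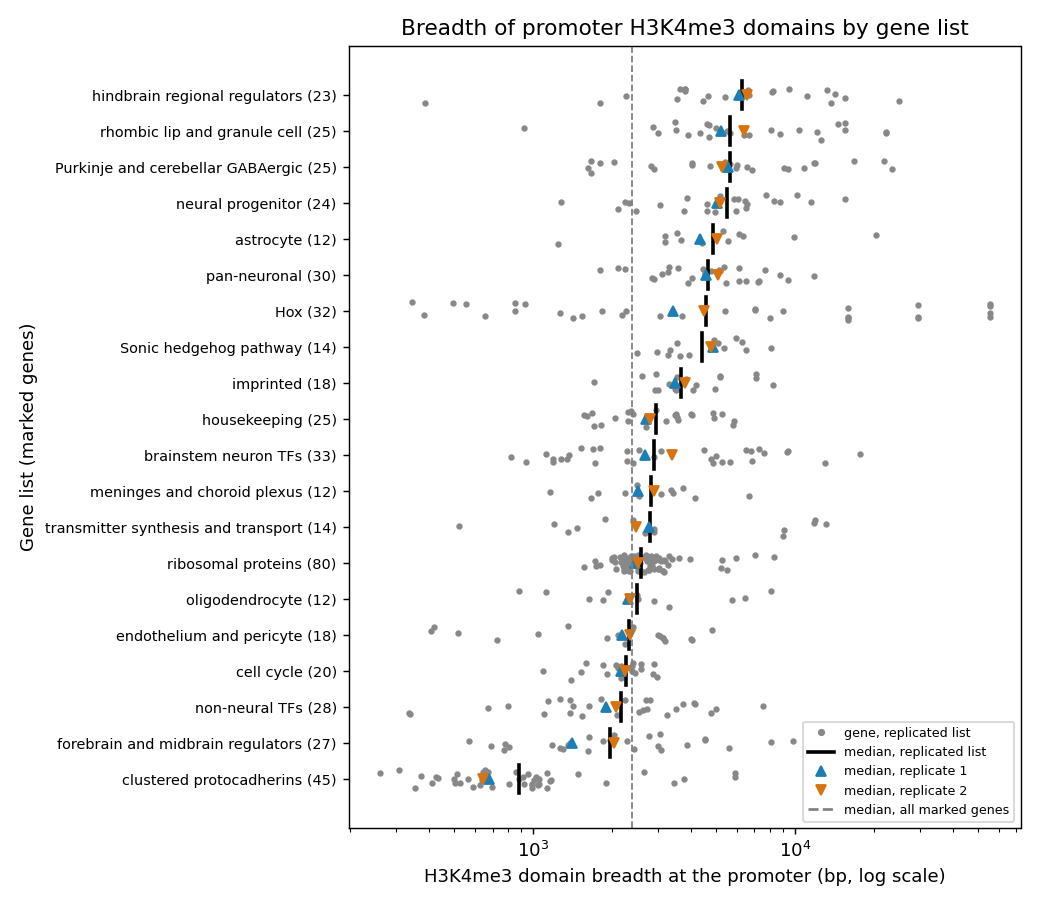
Breadth of the H3K4me3 domain at the promoter (x axis, bp, log scale) of each marked gene (grey points) in the 20 lists tested (y axis, with the number of marked genes). Black bars are list medians in the replicated list, triangles the medians in each replicate, and the dashed line the 2381 bp median of all marked genes; hindbrain regional regulators lie highest at 6268 bp and clustered protocadherins lowest at 885 bp.

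The broadest single domains of protein-coding genes lay over transcription factor genes, ordered here by span in the replicated list. The widest spanned Hoxb3, Hoxb4, Hoxb5 and Hoxb6 on chromosome 11 (96291570 to 96347060, mm10), at 55491 bp (55644 ± 439 bp in the replicates, SD, n = 2). The next covered Hoxa1, Hoxa2, Hoxa3 and 5730596B20Rik on chromosome 6 (52156348 to 52185726) at 29379 bp (29264 ± 163 bp, SD, n = 2). Hoxa3 was counted here through another annotated TSS, as its 5' end lies outside this domain. Then followed Nr2f2 on chromosome 7 (70345639 to 70371374, 25736 bp), Meis2 on chromosome 2 (116051673 to 116076583, 24911 bp) and Ebf3 on chromosome 7 (137299921 to 137323304, 23384 bp). Zic1 and Zic4 on chromosome 9 (91349871 to 91372195, 22325 bp), Lhx1 on chromosome 11 (84512379 to 84534193, 21815 bp), Pou3f3 on chromosome 1 (42683981 to 42705140, 21160.0 bp) and Nfib on chromosome 4 (82493458 to 82513902, 20445 bp) came after these. The 5' end of Nfib lies outside its domain, which touches another annotated TSS of the gene. By the mean of the replicates Meis2 (25828 ± 1938 bp) came before Nr2f2 (25629 ± 205 bp). Nfib (20312 ± 21.9 bp) came before Lhx1 (19324 ± 1402 bp) and Pou3f3 (17856 ± 4269 bp, SD, n = 2). The Lhx1 domain reached the promoter of Aatf in replicate 2 but not in replicate 1, where Aatf measured 1840.0 bp, and Pou3f3 measured 14837 bp in replicate 1 and 20874 bp in replicate 2. The last of the 10 held Gata3, 4930412O13Rik and 9230102O04Rik on chromosome 2 (9872365 to 9890084, 17720.0 bp). In each replicate alone the Lhx5 domain (16715 and 17228 bp) was broader than that of Gata3 (16099 and 15991 bp).

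The broadest 5% of marked genes, 728 genes above 5462 bp, held 14 of 25 rhombic lip and granule cell genes, 13 of 25 Purkinje and cerebellar genes, 12 of 23 hindbrain regional regulators and 12 of 24 neural progenitor genes. They also held 15 of 32 Hox genes, 10 of 33 brainstem transcription factors and 10 of 30 pan-neuronal genes. Adjusted p for these 7 lists ranged from 3.9e-11 to 1.2e-05 by Fisher's exact test. Astrocyte genes (5 of 12, adjusted p = 6.2e-04), transmitter genes (5 of 14, adjusted p = 0.0013), Sonic hedgehog pathway genes (4 of 14, adjusted p = 0.011) and oligodendrocyte genes (3 of 12, adjusted p = 0.048) were over-represented too, by Fisher's exact test. Genes that share a domain were each counted, such as Hoxb3, Hoxb4, Hoxb5 and Hoxb6, or Zic1 and Zic4. The 32 marked Hox genes had 24 distinct domains, so the p of this list takes as separate genes that are not independent. Some lists share genes, so their counts are not independent. Gad1, Gad2 and Slc32a1 were counted in both the transmitter and the Purkinje lists. Meis1 was in the hindbrain and rhombic lip lists, Pax6 in the rhombic lip and progenitor lists, and Ascl1 in the Purkinje and progenitor lists. Cell cycle genes had 0 of 20 in this class and housekeeping genes 2 of 25 (adjusted p = 1 and 0.69, Fisher's exact test).

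Hox genes, which set position along the body axis, were compared between paralog groups 1 to 5, the anterior groups, whose expression reaches the hindbrain, and groups 6 to 13, which act mainly further back. All 15 genes of groups 1 to 5 were marked, against 17 of 24 genes of groups 6 to 13 (p = 0.031, Fisher's exact test). With unmarked genes at 0 bp, the median breadth was 15982 bp in groups 1 to 5 and 754 bp in groups 6 to 13. The replicates alone gave 15895 against 422 bp and 15903 against 329 bp (p = 2e-05 for each of the 3 lists, permutation test). The difference of 15228 bp fell to 7284 bp with the 5' end only (p = 0.0013, permutation test) and to 5956 bp without joining (p = 9.1e-04, permutation test), and rose to 36186 bp with joining over 3000 bp. Median enrichment of marked genes was 21.8 against 4.07. The broadest gene domains of the other clusters were those of Hoxd3 and Hoxd4 on chromosome 2 (15899 ± 5.7 bp, SD, n = 2) and Hoxc4 on chromosome 15 (8752 ± 148 bp, SD, n = 2). The 5' ends of Hoxd3, Hoxd4 and Hoxc4 lie outside these domains, which touch other annotated TSSs of the genes. Not all genes of groups 1 to 5 lay in broad domains, as Hoxb1 (1329.5 ± 152 bp, SD, n = 2) and Hoxd1 (1668.5 ± 248 bp, SD, n = 2) did not. The domains over Hoxb3 to Hoxb6 and over Hoxa5 and Hoxa6 (15794 ± 50.2 bp, SD, n = 2) held genes of both groups, and Hoxb7 and Hoxb8 shared 1 of 7466 ± 1299 bp (SD, n = 2).

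At the back of the clusters Hoxa9, Hoxa11, Hoxc9, Hoxc11, Hoxc12 and Hoxd12 had no peak at a TSS in either replicate, and Hoxa10 had a peak of 232 bp in replicate 1 only. Both replicates had a peak in the body of Hoxc9, away from its annotated TSSs. The marked genes Hoxa13, Hoxb13, Hoxc13 and Hoxd13 had domains of 676 ± 230 bp, 336 ± 18.4 bp, 287 ± 62.2 bp and 574 ± 63.6 bp (SD, n = 2). Also marked were Hoxa4, Hoxa7, Hoxb2, Hoxb9, Hoxc5, Hoxc6, Hoxc8, Hoxc10, Hoxd8, Hoxd9, Hoxd10 and Hoxd11. Hoxd11 in replicate 1 and Hoxd10 in replicate 2 measured 195 bp, the smallest peak width in these lists. In replicate 1 alone 18 of 24 genes of groups 6 to 13 were marked and the difference in marking did not pass (p = 0.065), nor did it with a 2500 bp window (p = 0.065) or with the 5' end only (p = 0.12, Fisher's exact test). Hox genes share domains (24 distinct domains for 32 marked genes), so their values are not independent.

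**Figure D3:**
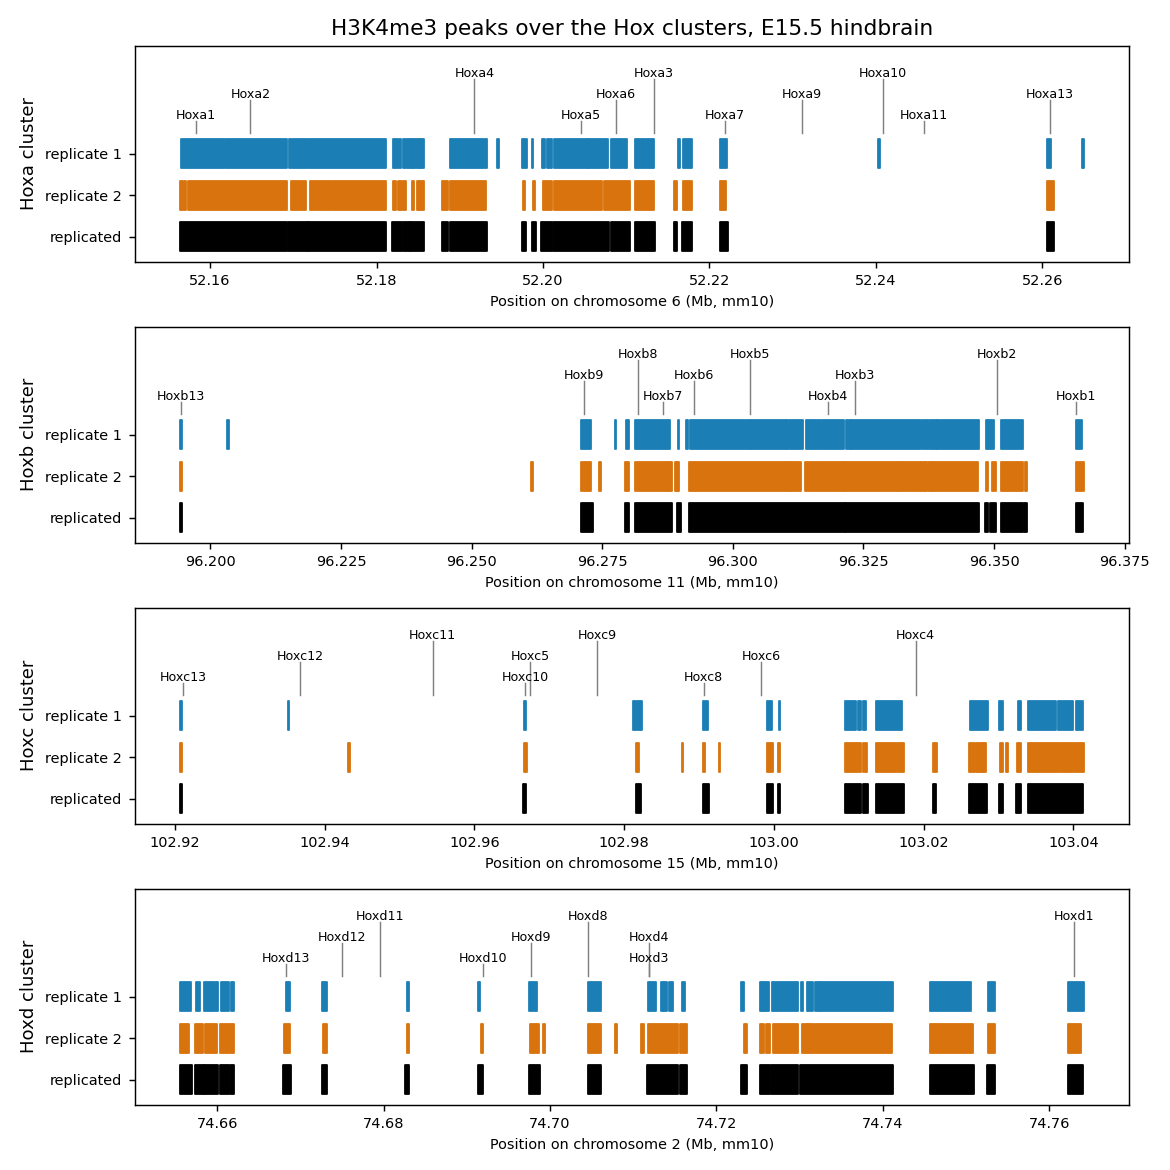
H3K4me3 peaks (bars) of replicate 1, replicate 2 and the replicated list (rows) over the 4 Hox clusters, by chromosome position (x axis, Mb, mm10), with the annotated 5' end of each Hox gene marked above. The widest domains, each made of several neighbouring bars joined, lie over Hoxb3 to Hoxb6 (55491 bp) and over Hoxa1 and Hoxa2 (29379 bp). The latter also touches an annotated TSS of Hoxa3 other than the 5' end shown. Short peaks lie over genes such as Hoxb1 (1425 bp), Hoxc10 (494 bp, with 224 and 309 bp in the replicates) and Hoxd11 (552 bp, with 195 and 278 bp in the replicates). The smallest peak width in each list is 195 bp.

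Non-neural transcription factors were marked more often than terminal genes of liver, gut, pancreas, blood, muscle, cartilage, bone and skin. They were marked in 28 of 40 cases (70.0%, 53.5 to 83.4), with Onecut1 (7464 ± 99.7 bp, SD, n = 2), which neurons also use, the broadest, and Tbx2 at 5489 bp in replicate 1 and 2149 bp in replicate 2. Of the 40 genes 4 were also in other lists, Eomes in that of the rhombic lip, Sox17 in that of endothelium, and Foxc2 and Prrx1 in that of the meninges. Gata1, Hand1 and Hnf1a, regulators of blood, heart and liver, had no peak in either replicate. Terminal genes of liver, gut and pancreas, erythroid cells, and muscle, cartilage, bone and skin together were marked in 12 of 67 cases (17.9%, 9.61 to 29.2; p = 1.0e-07, Fisher's exact test). Median promoter CpG content was 0.610 in the regulators and 0.230 in the terminal genes. With CpG content as a covariate the difference was not resolved, with a log odds ratio of 0.409 ± 0.688 (SE) and a likelihood ratio p of 0.56 in a logistic model over genes, beside the exact test above.

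Distal peaks were narrower and weaker than those near genes. They numbered 4167 (17.6% of the replicated list), with a median width of 630.0 bp against 1831 bp and a median enrichment of 5.39 against 33.3. In both replicates a peak overlapped 3761 of them (90.3%), beside 95.1% of the whole replicated list. That list was made with both replicate lists, so high shares follow from its selection. Of the 4167 distal peaks 1341 lay in the body of a protein-coding gene and 2826 outside any. A TSS of the RefSeq annotation lay within 1000 bp of 493 (11.8%, 10.9 to 12.9), where random placements gave 1.31%. The distal peak of highest enrichment (67.0, with 51.1 and 58.7 in the replicates) lay on chromosome 12 (8640076 to 8641753), 32381 bp from the TSS of Pum2. The next were on chromosome 1 (171037654 to 171039543, enrichment 65.0, nearest gene Fcgr3), chromosome 15 (74486827 to 74488447, 60.7, nearest gene Adgrb1), chromosome 8 (83874576 to 83877008, 52.6, nearest gene Adgrl1) and chromosome 1 (171101186 to 171103983, 52.4, nearest gene Cfap126). All 5 were intergenic in the GENCODE annotation, and those near Fcgr3, Adgrb1 and Cfap126 lay at a RefSeq TSS.

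X-linked genes were marked less often than autosomal genes. Of 948 protein-coding genes on X, 490 were marked (51.7%), against 14051 of 20807 on the autosomes (67.5%; odds ratio 0.514, p = 6.6e-23, Fisher's exact test). The gap was −7.23 percentage points against autosomal genes matched on promoter CpG (51.7% against 58.9%, p = 0.0020, the smallest that 1000 permutation draws can give). Without predicted genes and families in many copies it was −3.48 points (74.8% against 78.3%, p = 0.044, Fisher's exact test). On Y, 4 of 183 genes were marked (2.19%).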

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

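The gene tests left out the scaffolds that are not placed on chromosomes, and these carried 16 replicated peaks, above the limit of 3 that a count of 0 allows. This limit served only to decide what to list here and is no test, as no expected number of peaks was computed. The 16 peaks lay on 8 scaffolds with a median width of 644 bp and a median enrichment of 9.75. Of them 14 overlapped a peak in both replicates, from which the replicated list was made.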

How the results depend on the processing

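The alternatives were fixed before the data were examined, except those for the comparison of hindbrain with forebrain and midbrain regulators and the further sets of genes for the X-linked gap. Of the alternative values of the main results, 122 kept their direction and their side of the threshold or moved little, 9 moved and 3 lost their call. These main results leave out the calls of single gene lists. Of the alternative values of the other results, the single lists among them, 1059 stayed so, 284 moved, 16 reversed, 22 gained a call and 16 lost theirs. The cause was not tested unless stated. Spearman's rho of promoter enrichment between replicates was 0.876 with the −log10 p in its place. The lists called narrower numbered 1, and 2 with a −log10 q of at least 5 or with bases covered, and 3 with the 5' end only or without joining. From each replicate alone they numbered 1 to 2. The gap in marked Hox genes was 29.2 percentage points; it was 25 with a TSS window of 2500 bp (p = 0.065) and 26.7 with the 5' end only (p = 0.12), both by Fisher's exact test, and 25 to 29.2 from the replicates alone. The lowest CpG quartile was marked in 13.1% with the 2500 bp window. Against CpG-matched genes, 5 lists were marked more often and 4 less often, in place of 13 and 7. Reversed values belonged to lists without a call, except the breadth of Hox genes. For occupancy they were oligodendrocyte 66.7% (pooled list, and 2500 bp window) and 61.1% (5' end), meninges and choroid plexus 75% (pooled list), non-neural transcription factors 65.0% (−log10 q of at least 5) and 60.0% (5' end), and transmitter genes 65.0% (500 bp window) and 60.0% (5' end). Against CpG-matched genes non-neural transcription factors lay at −10.1 and Hox genes at −8.33 percentage points. For breadth, ratios to other genes were 0.978 to 1.02 (each replicate alone), 1.01 (nearest gene) and 1.09 (CpG-matched) for endothelial genes, which lay below 1 in the replicated list, 0.997 for brainstem (no joining), 1.61 for forebrain and midbrain (3000 bp joining) and 0.949 for Hox genes (nearest gene, a setting that removes shared domains). Breadths of 87 named genes were remeasured in each replicate alone, and 20 of 174 values moved by over 1.5 times. No paired analysis was possible because there is 1 group. Read depth is unknown, so weak or missing peaks cannot be read as absence of the mark.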

Other observations

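Some long non-coding RNA genes lay in broad domains. Of 10155 such genes 2636 (26.0%, 25.1 to 26.8) were marked, and of the 7074 with no protein-coding TSS within 5000 bp, 690 (9.75%, 9.07 to 10.5) were, with a median breadth of 1239 bp beside 2381 bp for marked protein-coding genes, a difference that was not tested. The broadest domains among the latter, marked in both replicates, belonged to C130071C03Rik on chromosome 13 (83713481 to 83742917; 29354 and 29446 bp in the replicates), Gm44946, whose domain is that of Nr2f2 on chromosome 7, and Mir124-2hg on chromosome 3 (17783691 to 17799543; 15824 and 16806 bp). Mir9-3hg, host of a microRNA of neural progenitors (12624 and 15874 bp), Sox2ot, whose domain also covers Sox2 (9582 and 10847 bp), and Malat1 (9426 and 9516 bp) were also among the 10 broadest. These genes were chosen after their values were seen.

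The tests of the next 2 paragraphs were chosen only after the results were seen. Hindbrain regional regulators lay in broader domains than forebrain and midbrain regulators, at a median of 6268 against 1971 bp (ratio 3.18, p = 3e-05, permutation test), although nearly all genes of both lists were marked. Their median enrichment was 29.7 against 7.97 (p = 1.5e-04, permutation test). The tables argue against promoter CpG content (ratio 2.54 of geometric means with CpG as a covariate), against the joining of peaks (3.79 without joining) and against the number of annotated TSSs (3.98 with 1 TSS per gene) as the whole cause, although joining over 3000 bp lowered the ratio to 2.08 (p = 0.032, permutation test). The ratio of 2.54 is of geometric means and that of 3.18 of medians, so their difference does not measure the part that goes with CpG content. No biological explanation was tested, since expression and repressive marks were not analysed here.

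Promoters marked in 1 replicate only numbered 185. Of these, 78.4% rested on a peak with a −log10 q under 5, and 26.5% had a peak of the other replicate within 2500 bp of a TSS. Only 1.18% and 1.10% of the 14495 genes marked in both rested on such a weak peak in replicate 1 and replicate 2, so weak peaks are a likely source. The lists reach down to a −log10 q of 0.192 and 0.218, so these peaks need not lie near the calling threshold, which is unknown. Requiring a −log10 q of at least 5 left the agreement at 98.8%, with 176 genes in 1 replicate only, of which 136 were marked in both with all peaks. Peak edges at the border of the TSS window stay open for the 185 genes as a set. The interval of the 26.5% (20.3 to 33.5%) holds the bound of 25% set for it, and no comparison share was computed. Agreement between replicates was 98.8% with a 2500 bp window beside 98.7%. Of the 40 genes not resting on a weak peak, 17 had a peak of the other replicate within 2500 bp. The named genes of highest enrichment are border cases, since their peaks exceeded every peak without a partner (at most 7.24 and 7.91). No biological explanation was tested, since both replicates belong to 1 group.

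X-linked promoters were marked less often than autosomal ones, and the tests in this paragraph were chosen after that gap was seen but before their own values, except the removals 1 kind at a time, which were added after. Promoter CpG content is lower on X, at a median of 0.387 against 0.568, but does not account for the whole gap: X-linked genes lay at −7.23 percentage points relative to CpG-matched autosomal genes (p = 0.0020, the smallest that 1000 permutation draws can give). Without predicted genes and families in many copies the X minus autosome gap was −3.48 points (74.8% against 78.3%, p = 0.044, Fisher's exact test), but it was −12.2 points without the families alone and −10.7 without the predicted genes alone, so the part of the families stays open. Marked X-linked genes had 0.811 times the enrichment of CpG-matched autosomal genes (p = 0.0020, permutation draws), but this value is a ratio over control and does not measure coverage, so lower coverage of X in embryos of both sexes stays open. The sex of the embryos is not given, and X inactivation was not tested.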
